A study of Homo sapiens with 13 samples.

How the data were processed

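RNA binding was measured by HITS-CLIP, with immunoprecipitation through a Flag tag, in 4 WT and 4 P95H samples of HEL cells given doxycycline at 1 µg/ml for 36 hours. RNA was measured after rRNA depletion in 2 WT and 2 P95H samples given doxycycline for 48 hours and in 1 P95H sample labelled uninduced, for 13 samples in all. Groups and replicate numbers were taken from the labels.

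The RNA-seq values are raw counts per Ensembl gene, as the authors deposited them. The submitters' processing notes name STAR 2.5.3a, TopHat2 2.0.14, edgeR and the genome build GRCh38.p3, without saying what each was used for. Which program counted reads, whether it used strand and which annotation release it read are not given in the sources used here. The HITS-CLIP table holds the authors' own comparison of P95H with WT in windows of 20 or 21 nucleotides. Per the file headers it gives a log2 change of P95H over WT, which the authors computed and deposited. The authors' adjusted p (FDR, an adjusted p-value as deposited) accompanies it, and how it was adjusted is not stated. Mean CPM per genotype and the standard error of that mean, also computed and deposited by the authors, complete the table, and the total to which CPM refer is not stated. Of 8324 entries, 224 repeated a position and were counted once, leaving 8100 windows. Each entry had an adjusted p of at most 0.05 and a change of at least 2-fold, so windows that were tested without passing were not part of it.

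Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr, libraries were scaled by TMM (factors from 0.958 to 1.04), and groups were compared by edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. P95H against WT used the 4 replicated libraries, and both comparisons with the library labelled uninduced used all 5, with the spread taken from the replicated groups. CPM in the text are TMM-scaled and log2 CPM had a prior count of 2. The batch fit added a term for batch, which is the replicate number in WT and P95H, with the library labelled uninduced placed in the batch of the replicate 2 libraries by its mitochondrial share, and as an alternative with the replicate 1 libraries. Same-numbered WT and P95H libraries deviated from their group means together, with a correlation of 0.722 across genes. Whether the numbers stand for a shared day or culture is not given in the sources used here.

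In all, 25 gene lists were fixed before the data were examined, with 465 of 483 listed symbols matched. They were SR proteins, hnRNPs, U2 snRNP and tri-snRNP components, SR protein and CLK kinases, genes reported as mis-spliced in SRSF2-mutant cells, nonsense-mediated decay factors, erythroid, megakaryocyte and platelet, myeloid, lymphoid, and epithelial and fibroblast genes, cell cycle genes, p53 targets, unfolded protein and integrated stress response, NF-kappa-B and inflammatory, interferon-stimulated and JAK-STAT target genes, mitochondrially encoded and nuclear oxidative phosphorylation genes, histones, ribosomal protein genes, heat shock genes, cholesterol synthesis genes, haematopoietic transcription factors and MDS genes, and abundant nuclear noncoding RNAs. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted by Benjamini-Hochberg over lists. With an estimated correlation camera takes its degrees of freedom from the fit, 2 on group alone and 1 in the batch fit. A list could then hardly pass, so a lost call does not show that its members are correlated. Members were counted over all genes and adjusted over the list alone.

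The genes named were to be SRSF2, the 8 largest rises and 8 largest falls past the threshold with a mean log2 CPM of at least 1 and groups that did not overlap, and up to 4 members of each list past the threshold, or 2 where none passed. No gene passed in the fit on group alone. The rule was therefore applied to the calls of the batch fit, without the condition on overlap in P95H against WT, a choice made after the values were seen. There the 8 largest rises and 8 largest falls had instead to have the same sign in both pairs of same-numbered libraries. For the comparisons with the library labelled uninduced, the genes named outside the lists were also picked after their values were seen, as were list members named without passing. Some genes that the rule takes are not reported. For HITS-CLIP the rule took 8 genes in each direction and up to 4 members of each list, and genes with the most windows were named after their values were seen.

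HITS-CLIP windows were processed in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures drawn with matplotlib 3.10.9. Overlapping windows of the same strand and direction were merged into regions, each assigned to the gene and transcript class of its window with the smallest adjusted p in the authors' deposited table. Transcript classes and list directions were compared by Fisher's exact test, two-sided. As windows tested without change were not part of the table, list members with a window were compared with 10000 draws of genes matched on RNA level (20 bins) and gene length (5 bins). Binding and RNA were related by Spearman correlation with 100000 permutations, two-sided. A lower and an upper bound on the share of a group's signal held by 1 library were computed from the standard error and the mean.

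The RNA-seq fits were tested on simulated data with the same library sizes and the spread of each fit. The batch shift was simulated for the batch fit alone. For the fit on group alone the libraries varied independently, unlike the real ones, so its recovery does not describe them. The fit on group alone recovered 58.2% of 2-fold changes for P95H against WT, 37.3% for P95H and 38.8% for WT against the library labelled uninduced. The batch fit recovered 95.5%, 92.5% and 86.6%, with 9, 6 and 7 false calls among the unchanged genes, against 16, 18 and 11 in the fit on group alone. For the batch fit the simulated library labelled uninduced carried the replicate 2 batch shift and no difference of its own. As that placing is not settled, batch-fit recovery and false calls against that library hold under that placing alone. At 4-fold the fit on group alone recovered 95.5%, 95.5% and 90.9%. The test of list direction was tested on simulated data with 20 planted genes and gave an adjusted p of 6.61e-09, with 0 other lists past the threshold by Fisher's exact test.

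Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, a filter at 1 CPM in 2 libraries, the replicate block, all 5 libraries in 1 fit, leaving out each library, and an adjusted p under 0.01 for windows. Agreement of comparisons that share libraries was set beside 100 simulated draws of unchanged groups. The motif content of bound sites was not analysed here, as it needs genome sequence, and splicing was not analysed here, as the counts are per gene. Tests across single HITS-CLIP libraries were not made, since the table gives means per genotype. Floors of 3 counts cover counting error alone.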

Results

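The series measured RNA binding by the splicing factor SRSF2 and the RNA content of HEL cells, a human erythroleukemia line. Cells carried a stable, doxycycline-controlled SRSF2 construct, either wild type (WT) or with the P95H change, a substitution recurrent in myelodysplastic syndromes. HITS-CLIP, in which RNA crosslinked to a tagged protein is recovered and sequenced, was made from 4 WT and 4 P95H samples after 36 hours of doxycycline. RNA-seq after rRNA depletion was made from 2 WT and 2 P95H samples after 48 hours, and from 1 P95H sample labelled uninduced. The labels call the numbered samples biological replicates, and nothing more is said of how the cultures were kept apart.

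The RNA-seq libraries held 45005605 and 42112595 counts for WT replicates 1 and 2, 38052389 and 44618943 for P95H replicates 1 and 2, and 37414093 for the library labelled uninduced. At these depths 3 counts corresponded to 0.0667 to 0.0802 CPM, the count scaled to the library total. The 4 replicated libraries fell into 2 batches by replicate number, which did not follow genotype. Mitochondrially encoded protein genes took 1.38% of the counts in both replicate 1 libraries, but 4.50% in WT replicate 2, 4.30% in P95H replicate 2 and 4.14% in the library labelled uninduced. Log2 CPM across genes correlated at r = 0.991 between WT and P95H libraries of the same number, above the r = 0.984 between the replicates of either genotype. Each RNA-seq comparison is therefore given as a fit on group alone and as a batch fit that adds the batch as a term. The batch fit of P95H against WT, where the batch is the replicate number, was among the alternatives chosen before the data were examined, and its use as a second fit beside the first was decided after. Placing the library labelled uninduced with the replicate 2 libraries, by its mitochondrial share, was also decided after. Its correlations were r = 0.989 with P95H replicate 2, 0.986 with WT replicate 2, 0.985 with WT replicate 1 and 0.984 with P95H replicate 1, all below the 0.991 within a number. Whether it belongs to either batch is thus not settled, and batch-fit values against it rest on that placing. The batch fit was therefore also run with it among the replicate 1 libraries, called the other placing below.

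SRSF2 transcripts were measured first, since the construct encodes SRSF2 itself (ENSG00000161547, chromosome 17, 76734115 to 76737374, minus strand, GRCh38). The gene stood at 232 ± 13.6 CPM in WT (SD, n = 2), at 237.5 ± 20.5 CPM in P95H (SD, n = 2) and at 285 CPM in the library labelled uninduced. The log2 difference was 0.05 (SE 0.11) between P95H and WT, -0.26 (SE 0.14) between P95H and the library labelled uninduced, and -0.30 (SE 0.14) between WT and that library. None of these passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p of 0.9999 for P95H against WT. In the other placing of the library labelled uninduced, the batch fit put SRSF2 below it in P95H (-0.34, edgeR adjusted p 0.00625) and in WT (-0.37, edgeR adjusted p 0.00206). In the first placing it gave -0.19 and -0.23, neither past edgeR's test. On group alone the P95H value was -0.16 without P95H replicate 1 and -0.36 without P95H replicate 2, and the WT value -0.24 without WT replicate 1 and -0.35 without WT replicate 2. Leaving out WT replicate 1 turned the P95H against WT value to -0.015, and leaving out P95H replicate 2 turned it to -0.056. The counts thus did not separate the library labelled uninduced from the others by a lower SRSF2 level. They cannot tell the construct from the endogenous gene, and they would include reads of the antisense neighbour MFSD11 if strand was not used in counting.

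The comparison of P95H with WT asks how RNA levels differ between cells carrying the mutant and the normal factor. Several genes of platelet and megakaryocyte function were lower in P95H within both batches. ITGB3, the beta-3 subunit of the platelet fibrinogen receptor, fell from 113 to 72.8 CPM between the replicate 1 libraries and from 193.5 to 124.7 CPM between the replicate 2 libraries, a log2 change of -0.62 in the batch fit (SE 0.08, edgeR adjusted p 4.72e-06). THBS1, which encodes the platelet granule protein thrombospondin, fell by 0.65 on the log2 scale, PLEK, the protein kinase C substrate pleckstrin, by 0.38, and TUBB1, the platelet beta-tubulin, by 0.44. These 4 were the members of the 19 megakaryocyte and platelet genes tested that passed the batch fit, with 1 up and 5 down when adjusted over the list alone. VWF, the von Willebrand factor gene, stood at -0.40 and GP1BA, a platelet glycoprotein gene, at 0.34, and neither passed over all genes. In the fit on group alone the list had a median log2 change of -0.11 with 13 of 19 members negative (camera adjusted p 0.0275; adjusted p = 0.788 with an estimated correlation). Its median was -0.17 between the replicate 1 libraries and 0.06 between the replicate 2 libraries, and in the fit on group alone -0.03 without WT replicate 1, -0.03 without WT replicate 2 and -0.17 without P95H replicate 2. In that fit, without WT replicate 2, ITGB3 stood at -0.19, PLEK at -0.23, THBS1 at 0.31 and TUBB1 at 0.17. Without P95H replicate 1 the same 4 stood at -0.29, -0.23, -0.20 and -0.11, against -0.96, -0.51, -1.31 and -0.92 without WT replicate 1.

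Erythroid genes were also lower as a group. In the fit on group alone, 21 of 24 had a negative change, with a median log2 change of -0.14 (camera adjusted p 0.00346; adjusted p = 0.788 with an estimated correlation), and medians of -0.09 and -0.18 within the 2 batches. HBE1, the embryonic beta-like globin, was the member past the batch fit and fell by 1.58, from 2.58 to 0.380 CPM and from 14.5 to 6.24 CPM. Adjusted over the list alone, 4 members were down. Without WT replicate 2 the fit on group alone put HBE1 at 0.37. HBD, the delta globin, stood at -0.41 and GATA1, a master regulator of erythroid genes, at -0.18 in the batch fit, neither past the test. Reads of globin genes can be split among near-identical copies. NF-kappa-B and inflammatory genes had a median of -0.19 with 14 of 16 negative (camera adjusted p 0.0069; adjusted p = 0.788 with an estimated correlation) and medians of -0.17 and -0.26 within batches. The chemokine CXCL8 fell by 0.83 in the batch fit and IL6, a cytokine, stood at -0.82 without passing. Adjusted over the list alone, 1 member of this list was up and 3 were down.

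The p53 target genes had a median log2 change of -0.11, with 12 of 17 negative (camera adjusted p 0.0438; adjusted p = 0.788 with an estimated correlation). The cell cycle inhibitor CDKN1A fell by 0.65 and the stress-induced SESN2 by 0.69 in the batch fit, and 2 members were also down when adjusted over the list alone. SESN2 stood at 0.021 in the fit on group alone without WT replicate 1, and CDKN1A at -0.11 without WT replicate 2 and -0.41 without P95H replicate 1. Haematopoietic transcription factors and MDS genes had a median of -0.07 with 25 of 30 negative, and nuclear oxidative phosphorylation genes one of -0.09 with 19 of 21 negative (camera adjusted p 0.0275 for each; adjusted p = 0.788 with an estimated correlation for each). GFI1, a transcriptional repressor of blood progenitors, was the member of the former past the batch fit, fell by 0.47 and was the member down when adjusted over the list alone, but stood at 0.16 in the fit on group alone without WT replicate 2. No oxidative phosphorylation gene passed, over all genes or adjusted over the list alone, and that list had medians of -0.17 and 0.01 within batches.

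Across all genes the batch fit called 41 higher and 43 lower in P95H. Among these calls, those with a mean log2 CPM of at least 1 and the same sign within both batches were ranked. The 8 largest rises were in LMO3, TMC8, MAGEC1, CPA3, RP11-80I3.1, A2M, RP11-574O16.1 and OLMALINC, from 1.29 for the LIM-domain gene LMO3 (edgeR adjusted p 0.00528) to 0.80 for the long noncoding OLMALINC (edgeR adjusted p 0.0486). The largest falls were in CCNA1, a germ-line and leukemia cyclin (log2 change -1.81, edgeR adjusted p 1.38e-05), HBE1, the gelatinase MMP2 (-1.01), WFDC1 (-0.99), the serine protease PRSS23 (-0.93), the BH3-only gene BMF (-0.92), CXCL8 and CPT1A (-0.79), whose product brings long-chain fatty acids into mitochondria. In the fit on group alone without WT replicate 2, CCNA1 stood at 0.99, PRSS23 at 0.84, CPT1A at 0.41, WFDC1 at 0.13, OLMALINC at -0.061, CPA3 at -0.073, BMF at -0.044, MMP2 at -0.21, CXCL8 at -0.38, TMC8 at 0.44 and PTBP2 at 0.13. Without P95H replicate 1, CPA3 stood at -1.5, A2M at 0.27 and MMP2 at -0.49, and without P95H replicate 2 LMO3 stood at 0.77, RP11-574O16.1 at 0.31 and NEAT1 at 0.09. NEAT1, the scaffold RNA of paraspeckles, rose by 0.41 and PTBP2, a splicing repressor, by 0.36. Both were members of lists, abundant nuclear noncoding RNAs (11 tested, 2 up adjusted over the list alone) and hnRNPs (27 tested, 1 up adjusted over the list alone), whose camera tests did not pass.

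**Figure D1:**
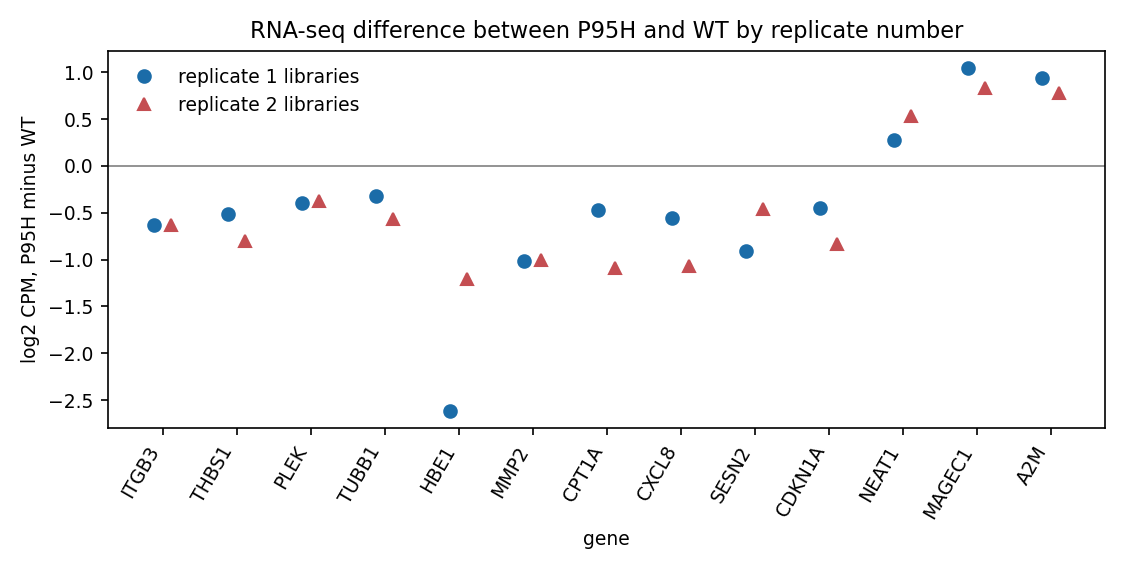
Log2 CPM difference between P95H and WT (vertical axis) for 13 genes (horizontal axis), with circles for the replicate 1 libraries and triangles for the replicate 2 libraries. Both points lie on the same side of 0 for each gene shown, at -0.63 and -0.63 for ITGB3. The genes were picked from those that passed the batch fit, and the largest changes had to have the same sign in both pairs. This agreement thus follows from the selection.

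Without the batch term no gene passed. EdgeR's quasi-likelihood test called 0 of 22007 genes, with 227 at an unadjusted p under 0.05, and DESeq2 called 0, with 98 at an unadjusted p under 0.05. On simulated counts that fit recovered 58.2% of genes changed 2-fold and 8.96% of those changed 1.5-fold, against 95.5% and 82.1% for the batch fit, which leaves 1 residual degree of freedom. The counts simulated for the fit on group alone held no shared batch, so its recovery does not describe these libraries. Without a filter on low counts edgeR called 15 genes (2 up, 13 down). In the fit on group alone, leaving out 1 of the 4 libraries leaves 1 batch with a single genotype, so such values mix the batch difference with that of genotype. CCNA1, for example, stood at 18.4 CPM in WT replicate 2 against 1.15, 0.836 and 3.70 CPM in the other WT and the P95H libraries. Leaving out WT replicate 2 turned the erythroid median, negative within both batches, to 0.17 (camera adjusted p 0.126) and ended the camera calls of NF-kappa-B genes (adjusted p 0.288) and p53 targets (adjusted p 0.383). The erythroid median was -0.48 without WT replicate 1 and -0.40 without P95H replicate 2. Leaving out P95H replicate 1 turned it to 0.05 (camera adjusted p 0.615) and ended the camera calls of the NF-kappa-B (adjusted p 0.205), megakaryocyte (adjusted p 0.524), oxidative phosphorylation (adjusted p 0.166) and p53 (adjusted p 0.416) lists. Leaving out WT replicate 1 ended those of haematopoietic factors (adjusted p 0.120) and oxidative phosphorylation (median 0.01, camera adjusted p 0.9), and leaving out P95H replicate 2 ended them too (camera adjusted p 0.163 and 0.0866). A stricter filter on low counts ended the camera calls of 4 lists, megakaryocyte, oxidative phosphorylation and p53 (adjusted p 0.0612 for each) and haematopoietic factors (adjusted p 0.0785).

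The other 19 lists did not pass camera in the fit on group alone, with adjusted p from 0.0573 for heat shock genes to 0.996 for genes reported as mis-spliced in SRSF2-mutant cells. Among lists of splicing factors, median log2 changes were 0.06 for SR proteins, 0.00 for hnRNPs, -0.04 for U2 snRNP and tri-snRNP components and 0.05 for SR protein and CLK kinases. For nonsense-mediated decay factors the median was -0.01 and for the mis-spliced genes -0.01. Markers of other blood or tissue cells had medians of 0.16 for myeloid, 0.49 for lymphoid and -0.18 for epithelial and fibroblast genes. The remaining medians were -0.04 for cell cycle, -0.15 for unfolded protein response, -0.10 for interferon-stimulated and 0.00 for JAK-STAT target genes. They were 0.01 for mitochondrially encoded, -0.04 for histone, -0.01 for ribosomal protein, -0.06 for heat shock, 0.07 for cholesterol synthesis and 0.06 for abundant noncoding RNA genes. The 6 lists called above passed camera in the batch fit too, with adjusted p up to 0.00672, and so did 4 of these 19. They were cholesterol synthesis (14 of 16 positive, median 0.08, camera adjusted p 0.00211), unfolded protein response (12 of 20 negative, median -0.12, adjusted p 0.00213), heat shock (12 of 13 negative, median -0.05, adjusted p 0.0179) and interferon-stimulated genes (14 of 18 negative, median -0.10, adjusted p 0.0473). For all 10 camera gave adjusted p = 0.785 with an estimated correlation. That version rested on 1 residual degree of freedom and could hardly pass. Erythroid genes had an estimated correlation of -0.0145, below the preset 0.01, yet the unadjusted camera p went from 3.92e-10 to 0.0911. Such lost calls thus do not by themselves show correlation between members. In the fit on group alone, estimated correlations were 0.478 for erythroid, 0.448 for oxidative phosphorylation, 0.0794 for megakaryocyte and 0.0646 for NF-kappa-B genes. These lay above the preset 0.01, so camera at the preset may overstate those calls. Estimates for p53 targets (0.00614) and haematopoietic factors (-0.0164) lay below it. No cholesterol, heat shock or interferon-stimulated gene passed the batch fit over all genes and 1 unfolded protein response gene fell. Adjusted over the list alone 4 cholesterol genes rose, and 3 unfolded protein response, 1 heat shock and 1 interferon-stimulated gene fell. No member of any of the 25 lists passed edgeR's test in the fit on group alone, over all genes or adjusted over the list alone.

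Comparing P95H libraries after doxycycline with the library labelled uninduced asks how RNA levels differ with the labelled induction of the mutant, which SRSF2 counts did not show. Genes of cholesterol synthesis were lower in the P95H libraries labelled as given doxycycline. All 16 had a negative log2 change, with a median of -0.60 (camera adjusted p 7.47e-09; adjusted p = 0.777 with an estimated correlation). In the batch fit 11 of the 16 fell, or 15 adjusted over the list alone, and 15 of 16 were negative with DESeq2 size factors. INSIG1, a sterol-regulated ER anchor, fell by 1.29, the lanosterol synthase LSS by 1.23 and DHCR7, the last enzyme of the Kandutsch-Russell route, by 1.10. Median differences of the list from the library labelled uninduced were -0.61 in P95H replicate 1 (11 of 16 lower) and -0.56 in P95H replicate 2 (16 of 16 lower). Adjusted over the list alone, the fit on group alone called 4 of the 16 down. The batch fit in the other placing had 10 of the 16 negative at a median of -0.46, with 9 called down and 1 up, and put INSIG1 at 0.022, LSS at -0.39 and DHCR7 at -0.81.

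Several kinases of SR proteins were lower as well. The list of SRPK and CLK kinases had a median of -0.37 (camera adjusted p 0.0272, or 0.777 with an estimated correlation). Of its 9 members 6 were negative and 3 positive in that fit, and 5 negative and 4 positive in the batch fit. In the batch fit 5 of 9 fell, or 5 adjusted over the list alone, among them CLK1 (-0.72), CLK4 (-0.55) and CLK3 (-0.38), which phosphorylate SR proteins in the nucleus, and SRPK3 (-0.66). Of the 9, 3 fell in the other placing, or 4 adjusted over the list alone, with CLK3 at -0.36 and SRPK3 at -1.25, while CLK1 (-0.26, edgeR adjusted p 0.0988) and CLK4 (-0.25, edgeR adjusted p 0.259) no longer passed. SR protein genes had a median of 0.13 in the fit on group alone, where camera did not pass (adjusted p 0.141), and 3 rose in the batch fit, or 6 adjusted over the list alone. They included SRSF10 (0.36) and TRA2B (0.35). Camera called the list in the batch fit (median 0.21, 11 of 14 positive, adjusted p 0.000934; adjusted p = 0.783 with an estimated correlation). With the other placing camera did not (adjusted p 0.794), and SRSF10 (0.086) and TRA2B (0.092) did not pass edgeR's test. The hnRNP list had a median of 0.15 with 23 of 27 positive (camera adjusted p 0.00382; adjusted p = 0.777 with an estimated correlation), and none of its members passed the batch fit over all genes or adjusted over the list alone, HNRNPA1 standing at 0.29. With the other placing 5 of them rose and 1 fell, over all genes and adjusted over the list alone, HNRNPA1 being at 0.42 (edgeR adjusted p 0.000164).

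Ribosomal protein and histone genes were higher in the P95H libraries than in the library labelled uninduced. All 27 ribosomal protein genes were positive, with a median of 0.29 (camera adjusted p 1.32e-07; adjusted p = 0.777 with an estimated correlation), and RPL11 and RPS27A stood at 0.31 and 0.47 in that fit. None passed alone in the fit on group alone or in the batch fit, over all genes or adjusted over the list alone. Of the 27, 25 rose in the other placing, or 26 adjusted over the list alone, with RPL11 at 0.36 and RPS27A at 0.67. The list's difference was 0.39 in replicate 1 and 0.14 in replicate 2. The list's median was 0.11 in the batch fit, with 24 of 27 positive, and 0.16 without P95H replicate 1. All 15 replication-dependent histone genes were positive, with a median of 0.22 (camera adjusted p 2.69e-05; adjusted p = 0.777 with an estimated correlation). The linker histone genes HIST1H1D (0.63) and HIST1H1E (0.35) and the core histone gene HIST1H2BD (0.36) rose in the batch fit, and 4 members rose adjusted over the list alone. With the other placing 11 rose, or 13 adjusted over the list alone, with HIST1H1D at 0.31. Reads of histone genes can be split among similar copies. Interferon-stimulated genes had a median of 0.22 with 15 of 18 positive (camera adjusted p 0.0192; adjusted p = 0.777 with an estimated correlation), and 2 of them rose in the batch fit, or 3 adjusted over the list alone. In the other placing 2 rose and 1 fell, also adjusted over the list alone.

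The batch fit also called single stress-response genes. In it the stress-induced transcription factor ATF3 rose by 1.04 and PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2-alpha, by 0.85, while HERPUD1, an ER stress gene, fell by 0.62. The p53 targets BBC3, which encodes the pro-apoptotic PUMA, BTG2 and DDB2 rose by 1.74, 0.88 and 0.68, the immediate-early factor EGR1 by 1.51 and the chemokine CXCL8 by 1.47. In that fit camera called p53 targets (11 of 17 positive, median 0.10, adjusted p 0.000934) and NF-kappa-B genes (12 of 16 positive, median 0.09, adjusted p 0.0241), each at adjusted p = 0.783 with an estimated correlation. Neither passed camera in the other placing (adjusted p 0.414 and 0.738). There BTG2 stood at 0.0020, DDB2 at 0.12 and PPP1R15A at 0.14, none past edgeR's test, while BBC3 (1.1), CXCL8 (0.85), ATF3 (1.13), EGR1 (1.61) and HERPUD1 (-0.50) passed. FRG2FP, a pseudogene (log2 change 3.71), and ERN2, an epithelial ER stress sensor (3.39), had the largest of these rises from 0.213 and 0.240 CPM in the library labelled uninduced. The netrin NTN3 (-1.91), the kinase DYRK1B (-1.63) and the macrophage receptor gene VSIG4 (-1.44) fell. Of the megakaryocyte list, 2 rose and 3 fell in the batch fit, also adjusted over the list alone, the falls including the integrin ITGA2B (-0.50) and the platelet glycoprotein GP9 (-0.61). In the other placing 2 rose and 7 fell, or 8 adjusted over the list alone, ITGA2B was at -0.56, GP9 at -0.38 without passing (edgeR adjusted p 0.0571) and DYRK1B at -0.58.

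On group alone, edgeR called 0 of 23970 genes, with 818 at an unadjusted p under 0.05, and the batch fit called 215 higher and 651 lower. The batch fit in the other placing called 1184 higher and 2501 lower, and interferon-stimulated genes lost the camera call (adjusted p 0.216). DESeq2 called 7, of which FRG2FP and ERN2 were higher. The state labelled uninduced rests on 1 library, whose spread was taken from the other libraries. Mitochondrially encoded genes (median -0.50, camera adjusted p 0.0272) turned to 0.09 in the batch fit (camera adjusted p 0.000953; adjusted p = 0.783 with an estimated correlation) and 0.14 without P95H replicate 1, and stood at -1.57 in the other placing. The library labelled uninduced was placed by its mitochondrial share. The batch-fit value of this list near 0 thus followed from the placing, and its camera call there is no separate result. Erythroid genes (median -0.18, camera adjusted p 0.0272) moved to 0.00 (adjusted p 0.428) in the batch fit and, without P95H replicate 1, lost the call (camera adjusted p 0.689). For both lists the adjusted p = 0.777 with an estimated correlation in camera. Without P95H replicate 2 they stood at -1.60 and -0.56. Without that library the camera calls of kinases, hnRNPs and interferon-stimulated genes ended (adjusted p 0.0627 for each) and 11 of 16 cholesterol genes were negative. The kinase, erythroid and mitochondrial calls also ended without a filter on low counts (camera adjusted p 0.0597, 0.0597 and 0.0964) and with a stricter one (0.0566, 0.0576 and 0.0566). The 17 other lists did not pass camera in the fit on group alone, with adjusted p from 0.1 to 0.876. Camera called 14 lists in the batch fit. Besides p53 targets, NF-kappa-B genes and SR proteins, those new in it were cell cycle genes (24 of 30 positive, median 0.13, camera adjusted p 0.000934), abundant noncoding RNAs (7 of 11, 0.08, 0.00977), U2 snRNP and tri-snRNP components (22 of 29, 0.05, 0.00977) and nonsense-mediated decay factors (14 of 17, 0.11, 0.0241). All of these had adjusted p = 0.783 with an estimated correlation. None of them passed camera in the other placing (adjusted p 0.736 for each of the last 4), where unfolded protein response (median 0.15, adjusted p 0.000965) and megakaryocyte genes (median -0.15, adjusted p 0.0108) did. Erythroid genes stood at -0.56 there, with 17 of 24 called down.

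Libraries of WT cells after doxycycline were set beside the same library, to see which of these differences also appear with the normal factor. Cholesterol synthesis genes were again lower, all 16 negative with a median of -0.61 (camera adjusted p 1.57e-10; adjusted p = 0.575 with an estimated correlation). Their median difference was -0.46 in WT replicate 1 (11 of 16 lower) and -0.77 in WT replicate 2 (16 of 16 lower), and 14 of 16 genes were negative with DESeq2 size factors. In the batch fit 12 fell, or 14 adjusted over the list alone, with LSS at -1.61, INSIG1 at -1.60 and DHCR7 at -1.27. In the other placing 12 of the 16 were negative and 10 fell, also adjusted over the list alone, where 2 rose, with LSS at -0.76, INSIG1 at -0.29 and DHCR7 at -0.97. CLK1 fell by 0.76, or 0.30 in the other placing, NTN3 by 1.99 and VSIG4 by 1.96, while ERN2 rose by 3.32, FRG2FP by 3.40 and ATF3 by 1.28.

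Histone genes (median 0.32, 15 of 15 positive), ribosomal protein genes (0.28, 27 of 27), hnRNPs (0.14, 23 of 27) and p53 targets (0.16, 14 of 17) were higher, with camera adjusted p of 1.22e-07, 2.98e-08, 0.00169 and 0.00213. With an estimated correlation camera gave adjusted p = 0.575, 0.670, 0.575 and 0.575. The estimates were 0.6415 for histone, 0.9765 for ribosomal protein, 0.1312 for hnRNP and 0.006915 for p53 target genes, against the preset 0.01. In the batch fit 5 histone genes and 6 p53 targets rose, or 8 and 7 adjusted over the list alone, and no ribosomal protein gene passed, over all genes or adjusted over the list alone. In the other placing 11 histone genes, 3 p53 targets and 26 ribosomal protein genes rose, or 15, 3 and 27 adjusted over the list alone. Without WT replicate 1 the histone median was 0.16 and the ribosomal one 0.12. Camera also called interferon-stimulated genes (median 0.26), NF-kappa-B genes (0.29), U2 snRNP and tri-snRNP components (0.09), cell cycle genes (0.08), oxidative phosphorylation genes (0.14), unfolded protein response genes (0.31), SR protein kinases (-0.26) and mitochondrially encoded genes (-0.47). The smallest of the adjusted p was 0.000448 and the largest 0.0484, and with an estimated correlation adjusted p ran from 0.575 to 0.849 in camera. Leaving out WT replicate 2 ended the camera calls of the first 4 of these and of the kinases (adjusted p 0.107, 0.191, 0.187, 0.451 and 0.0777). Leaving out WT replicate 1 ended those of oxidative phosphorylation, unfolded protein response and mitochondrially encoded genes (camera adjusted p 0.231 for each), the last at a median of 0.11 and of 0.15 in the batch fit. In camera the mitochondrially encoded, NF-kappa-B and unfolded protein response calls also ended without a filter on low counts (adjusted p 0.123, 0.0803 and 0.103), and the first and last of these with a stricter filter (0.0752 and 0.0572). The other 12 lists did not pass camera in the fit on group alone, with adjusted p from 0.0817 to 0.975. Camera called 18 lists in the batch fit, those new in it being erythroid (16 of 24 positive, median 0.13, adjusted p 5.13e-05), heat shock (10 of 13, 0.20, 0.00438), nonsense-mediated decay (12 of 17, 0.13, 0.0139) and SR protein genes (9 of 14, 0.15, 0.0207), and myeloid genes (10 of 13 negative, median -0.26, 0.0286). With an estimated correlation camera gave these adjusted p = 0.567 to 0.666. In that fit 5 erythroid genes rose, or 8 adjusted over the list alone. With the other placing camera called erythroid genes with the opposite sign (median -0.39, 10 called down and 1 up, adjusted p 7.23e-06) and none of the other 4 (adjusted p from 0.232 to 0.846). Mitochondrially encoded genes, positive in the batch fit and among its 18 lists, stood at -1.61 there. Their batch-fit value followed from placing the library labelled uninduced by its mitochondrial share.

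On group alone edgeR called 0 of 23970 genes, with 1122 at an unadjusted p under 0.05. DESeq2 called 6, of which ATF3, CXCL8, ERN2 and FRG2FP were higher and SLC29A2 and RP6-159A1.4 lower. Without WT replicate 1 edgeR called 2, SREBF1 and RP6-159A1.4, both lower. The batch fit called 476 genes higher and 937 lower, or 1318 and 2379 in the other placing. In that placing the NF-kappa-B, U2 snRNP and cell cycle lists lost the camera call (adjusted p 0.296, 0.206 and 0.214). Of the 476 and 937, 165 and 461 were also called, in the same direction, for P95H against the same library. Independent lists would share 4.27 and 25.5, but both comparisons use the same single library, so shared calls can arise without any change of WT or P95H, and how many was not simulated.

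Log2 changes of P95H and of WT against the library labelled uninduced correlated at r = 0.847 across 12929 genes, which are not independent replicates. Unchanged groups simulated against that library, with the batch shift, gave a mean of 0.839 over 100 draws, and 0.669 without it. The simulated batch shift had that library in the batch of the replicate 2 libraries, a placing that is not settled. The covariance was 0.0692, against 0.0468 in the simulation with the batch shift and 0.0645 without it. Of the genes 83.8% had the same sign, against 80.4% with the shift and 73.3% without it. The simulated comparisons share 1 library in the same way, so its sharing is already part of the simulated values. The size of the excess depends on the spread that was simulated. A difference particular to that single library, which cannot be split, could not be told from a change in both groups. Log2 changes of P95H against WT and of P95H against the library labelled uninduced, which share the P95H libraries, correlated at r = 0.147. This lay below the simulated 0.285 with the batch shift and 0.407 without it. The covariance was 0.00645, against 0.00903 with the shift and 0.0320 without it. Of the genes 53.9% had the same sign, against 59.8% and 63.4%. Neither simulation thus matched the observed values. The batch-fit calls shared 1 gene up and 5 down, where independent lists would share 0.397 and 1.26, which is not the number that the shared P95H libraries alone would give. Splitting the P95H libraries would leave 1 in each part, so these could not be told apart.

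HITS-CLIP asks where on RNA the mutant and the normal factor differ in binding. The authors' deposited table lists 8100 windows of 20 or 21 nucleotides with a changed signal, each with a change of at least 2-fold and an adjusted p of at most 0.05. Of these, the authors' deposited table gives a lower signal in P95H for 6297 and a higher one for 1803, which is 77.7% lower. Merging overlapping windows gave 2473 regions lower and 1269 higher, or 66.1% lower, from the authors' deposited table. By gene, the authors' deposited table held 1383 genes with lower windows alone, 745 with higher windows alone and 254 with both.

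Regions in different classes of transcript went in different directions. Of the regions in small and structural RNAs in the authors' deposited table, 54 of 72 (75%) were higher in P95H, and of those in long noncoding RNAs 134 of 244 (54.9%). Regions assigned to retained-intron transcripts were higher in 44.1% of cases in the authors' deposited table, those in protein-coding transcripts in 30.4% and those in pseudogenes in 26.7%. Against all other regions, Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over 7 classes, gave adjusted p of 5.73e-12, 1.24e-11, 0.000203, 5.36e-09 and 0.00321. Nonsense-mediated decay transcripts (36.5% higher, adjusted p 0.504) and processed transcripts (30.5%, adjusted p 0.376) did not pass Fisher's exact test. Counted as 1 region per gene from the authors' deposited table, long noncoding RNAs were higher in 80 of 160 cases (50%) and small and structural RNAs in 52 of 70 (74.3%), retained-intron transcripts in 45%, protein-coding ones in 34.5% and pseudogenes in 27.7%. All 5 passed Fisher's exact test there, with adjusted p of 0.00118, 1.56e-09, 0.0327, 0.00118 and 0.00118. Counting only windows with an adjusted p under 0.01 in the authors' deposited table ended the call for pseudogenes (Fisher's exact test, adjusted p 0.263). Regions or genes were the units of these tests, not libraries. Their p-values therefore do not measure the spread between the 4 libraries of a genotype. In 80.1% of all listed windows 1 library must have held more than 50% of the higher group's signal. Such windows were kept in these tests.

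**Figure D2:**
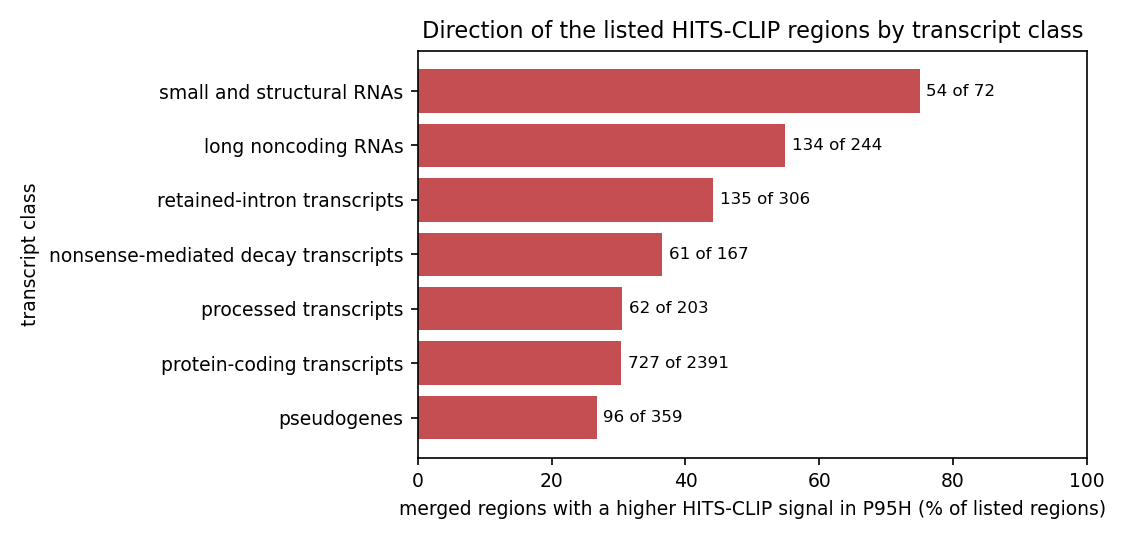
Share of merged regions with a higher signal in P95H, in percent (horizontal axis), for each transcript class (vertical axis), from the authors' deposited table, with the number higher of all listed written beside each bar. Bars run from 26.7% for pseudogenes to 75% for small and structural RNAs.

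Some genes held many windows, and those named here were picked after their values were seen. In the authors' deposited table the nucleolar protein gene NCL had 190 windows, the histone chaperone genes ANP32B and ANP32A had 108 and 58 and the high-mobility-group gene HMGB2 had 89, each of them lower in P95H. Many of these windows overlap, so they are not separate sites. Merged, they came to 12 regions for NCL, 8 for ANP32B, 9 for ANP32A and 8 for HMGB2. PTMA, the prothymosin gene, had 101 windows lower and 2 higher in the authors' deposited table, the chaperone HSP90AA1 had 69 lower and the translation factors EIF5B and EIF3A had 60 and 55 lower. Merged regions were 9 lower and 1 higher for PTMA, 6 lower for HSP90AA1, 11 lower for EIF5B and 10 lower for EIF3A. MALAT1, a nuclear speckle RNA, went both ways in the authors' deposited table, with 21 windows lower and 30 higher, or 9 merged regions lower and 16 higher. SRSF2's own RNA held a window in the authors' deposited table that was lower in P95H (chromosome 17, 76736366 to 76736386, log2 change -1.51, adjusted p 0.0163). By the deposited standard errors, 1 WT library must have held at least 85.06% of the WT signal there.

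Among the fixed lists, more U2 snRNP and tri-snRNP genes carried listed windows than did comparable genes. In the authors' deposited table a window was listed for 17 of 29 U2 snRNP and tri-snRNP genes, against a mean of 8.95 in 10000 draws of genes matched on RNA level and length, of which 0.09% reached as many. Of the 17 in the authors' deposited table, 11 had lower windows alone, 1 higher alone and 5 both, and examples were the helicase genes DDX23 (log2 -7.37), DDX46 (-3.81) and SNRNP200 (-4.78) and SF3B2 (6.48). By the deposited standard errors, 1 library must have held at least 84.85% of the higher group's signal for DDX23. That share was 49.74% for DDX46, 94.2% for SNRNP200 and 98.95% for SF3B2. Nonsense-mediated decay factors followed in the authors' deposited table with 9 of 17 against 4.49 (1.23% of draws), for example UPF3A (-3.93) and SMG1 (4.00). So did abundant noncoding RNAs with 5 of 11 against 2.22 (2.53%), SR proteins with 9 of 14 against 5.40 (3.16%), ribosomal protein genes with 19 of 27 against 14.2 (3.71%) and hnRNPs with 16 of 27 against 11.4 (4.35%), all from the authors' deposited table. In the authors' deposited table TRA2B (-5.73) and SRSF10 (-2.54) were lower, SRSF7 (4.75) and SRSF5 (4.10) higher, and HNRNPA1 (-4.37) and HNRNPM (-4.75) lower. Among these the smallest share that 1 library must have held ran from 33.89% for SRSF10 to 94.31% for SRSF7. With only windows at an adjusted p under 0.01 in the authors' deposited table, as many members were reached in 0.02% of draws for U2 snRNP and tri-snRNP genes and 0.67% for hnRNPs. At that limit in the authors' deposited table it was 5.37% for nonsense-mediated decay factors, 6.45% for noncoding RNAs, 7.91% for ribosomal protein genes and 12.6% for SR proteins. These shares of draws were not adjusted for the 25 lists.

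Direction within lists was compared with all other genes that had windows in 1 direction, by Fisher's exact test over 14 lists with enough such genes. The megakaryocyte and platelet list had 5 genes higher and 0 lower in the authors' deposited table, among them RUNX1 (log2 6.11), ITGA2B (2.28), THBS1 (3.58) and RAB27B (1.81), for a Fisher's exact p of 0.00521 and an adjusted p of 0.0730. By the deposited standard errors, 1 P95H library must have held at least 96.87% of the P95H signal for RUNX1 and 92.57% for RAB27B. It was 80.19% for ITGA2B and 37.18% for THBS1. Erythroid genes in the authors' deposited table had 5 higher, such as GATA1 (2.62) and RHAG (3.21), and 2 lower, such as ANK1 (-1.97), with a Fisher's exact p of 0.0554 and an adjusted p of 0.314. The U2 snRNP and tri-snRNP list, with mostly lower windows, had a Fisher's exact p of 0.0672, and the SR protein, hnRNP, ribosomal protein, nonsense-mediated decay and noncoding RNA lists had Fisher's exact p from 0.416 to 1. None of the 14 lists passed, nor did any of 12 with an adjusted p under 0.01 required of each window. Heat shock genes (4 lower, 0 higher), cell cycle genes (5 lower, 3 higher), haematopoietic and MDS genes (6 lower, 4 higher), oxidative phosphorylation genes (3 lower, 2 higher), unfolded protein response genes (3 lower, 1 higher) and JAK-STAT targets (1 lower, 3 higher) completed the lists tested from the authors' deposited table. In the authors' deposited table the cholesterol, NF-kappa-B, interferon-stimulated, lymphoid, myeloid and epithelial lists had 0 members with a window. The other lists had 3 (mis-spliced genes, among them INTS3 and HNRNPA2B1), 2 (p53 targets), 1 (mitochondrially encoded), 1 (histones) and 1 (kinases) in the authors' deposited table.

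The largest listed changes were against groups listed at 0. In the authors' deposited table the 8 genes with the largest rises, PIGG, ELMO1, CNP, TERF1, RHOT2, DENND3, ADAR and CDK12, were listed at 0 CPM in WT and at 2.51 to 3.79 CPM in P95H. The 8 with the largest falls in the authors' deposited table, NCL, GOLGA6L4, GOLGA6L5P, GOLGA6L17P, CHD4, GOLGA6L9, RRP1 and APC, were listed at 0 CPM in P95H and at 3.37 to 6.52 CPM in WT. The NCL window lay at chromosome 2, 231455402 to 231455422, and that of PIGG at chromosome 4, 532926 to 532946, on GRCh38 in the authors' deposited table. From the standard errors in the authors' deposited table, a single library must have held at least 87.9% of the group's signal in each of these 16 windows.

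Single libraries carried much of the signal elsewhere too. From the standard errors in the authors' deposited table, 1 of the 4 libraries must have held more than 50% of the signal of the higher group in 80.1% of windows. This was not confined to weak windows. Among the 810 windows with the highest signal in that group (47.04 CPM or more) it held for 93.7%. It held for 93.49% of the 630 strongest windows lower in P95H and for 74.03% of the 181 strongest windows higher in P95H. Windows on opposite strands that overlapped in the authors' deposited table had the same direction in 163 of 163 cases, and their WT CPM lay within 25% of each other in 137 of the 163. Which of 2 overlapping genes was bound was uncertain in those 137, SRSF2 and MFSD11 included. Pseudogenes held 12.6% of the windows in the authors' deposited table, 168 of them in 7 copies of PTMA and 156 in 14 copies of HMGB1, where reads may be shared with the parent gene.

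Binding and RNA changes were set side by side across 2133 genes with a window and a tested RNA level. The mean log2 change in the authors' deposited table and the RNA-seq log2 change of P95H against WT had a Spearman correlation of 0.0528 across genes, which are not independent replicates (permutation p 0.0148, two-sided, 0.0271 after Benjamini-Hochberg adjustment over 11 versions of the relation). Taking the site with the smallest adjusted p per gene gave 0.0445 (permutation p 0.0387, adjusted p 0.0585), and leaving out RNA-seq P95H replicate 2 gave 0.0439 (permutation p 0.0425, adjusted p 0.0585), neither past the threshold after adjustment. Within batches it was 0.0236 (permutation p 0.279) between replicate 1 libraries and 0.0565 (permutation p 0.00906) between replicate 2 libraries, and with the RNA change of the batch fit 0.0577 (permutation p 0.00781, adjusted p 0.0249). On group alone it turned to -0.0057 without RNA-seq WT replicate 2 and to -0.018 without P95H replicate 1, where the batch is mixed with genotype. RNA levels had a median log2 change of -0.03 in genes with lower windows alone and -0.02 in genes with higher windows alone. Of the genes with windows in the authors' deposited table, 11 of 2133 (0.516%) were called in the RNA-seq batch fit, against 73 of the other genes (0.367%), with a Fisher's exact p of 0.269, two-sided. The former had higher RNA levels, with a median log2 CPM of 6.14 against 1.64, which changes how readily a gene is called. Above a log2 CPM of 5, the calls were 8 with windows and 21 without (Fisher's exact p 0.660). THBS1 was an example of both, with a higher window in the authors' deposited table and a fall in RNA.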

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

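The batch term in the comparisons with the library labelled uninduced and its placing, merged regions, gene-wise shares, windows by library share, leaving out libraries in list and binding tests, and RNA folds of single pairs were chosen after the data were examined. Of 122 settings across comparisons, 91 kept a test's call and direction, or kept a count or share near the reported one (counts within 1.5-fold). Another 16 passed a threshold the reported value had not or raised a count, 8 fell below one or lowered a count, 3 moved and 4 turned in direction. Counts were compared by size alone, so a count could stay near while the genes or lists in it changed. For single named genes 677 of 690 settings kept the direction. Where values differ below, the cause was not tested.

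Without a filter on low counts edgeR called 15 genes for P95H against WT, 92 for P95H and 128 for WT against the library labelled uninduced. With the replicate block, a paired fit, the first comparison had 84 genes and 10 lists, and with the batch term the others had 866 genes and 14 lists, and 1413 genes. Placing the library labelled uninduced with replicate 1 in that fit gave 3685 and 3697 genes, SRSF2 at -0.34 and -0.37, both then past the threshold, and INSIG1 at 0.022 for P95H. DESeq2 called 7 and 6 genes in these others. With an estimated correlation, and with fry, 0 lists passed in each comparison. The former rested on 2 residual degrees of freedom on group alone and 1 with the batch term, and could hardly pass. Leaving out 1 library gave 5 to 12 lists and 0 genes for P95H against WT, and 0 to 2 genes for WT against the library labelled uninduced. SRSF2 ranged from -0.056 to 0.13 in P95H against WT and stood at -0.015 without WT replicate 1. A lone library of a group was assumed to vary like the others, and leaving out 1 library mixes batch with genotype.

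Across the fits that left out 1 library, log2 changes of P95H against WT ranged from -1.5 to 3.78 for CPA3, -0.061 to 1.92 for OLMALINC, -3.54 to 0.99 for CCNA1, -4.48 to 0.37 for HBE1, -1.79 to 0.13 for WFDC1 and -2.11 to 0.84 for PRSS23. They ranged from -1.82 to 0.41 for CPT1A, -1.55 to 0.31 for THBS1, -0.97 to 0.17 for TUBB1, -1.28 to 0.021 for SESN2 and -1.02 to 0.16 for GFI1. Of these 12 turns, 10 came without WT replicate 2, and the others without P95H replicate 1 for CPA3 and without WT replicate 1 for SESN2.

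Counted as merged regions the HITS-CLIP windows came to 3742, with 66.1% lower in P95H, and by gene 65.0% were lower. Where no library can hold 50% of the signal, 71.2% of 52 windows were lower. The odds ratio of pseudogenes was 0.83 at an adjusted p under 0.01 (Fisher's exact test, adjusted p 0.263). The correlation of binding with RNA was 0.0236 with the fold of the first pair and ranged from -0.0178 to 0.0677 without 1 RNA-seq library, with -0.00569 without WT replicate 2. No paired analysis was possible for HITS-CLIP because the table carries means per genotype. For that reason its normalization, test, filter, block and left-out libraries were not run, nor was motif content, which needs sequence. A change of at least 2-fold removed no window.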

Other observations

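The tests of the patterns weighed here were chosen after the results were seen, and the genes of the opening paragraph were picked after their values were seen. The annotated transcripts MIR3648-1 and MIR3687-1, which lie in ribosomal DNA repeats, were highest in the library labelled uninduced and lower in P95H than in WT. MIR3648-1 stood at 276 and 265 CPM in WT, 152 and 187 CPM in P95H and 415 CPM in the library labelled uninduced, and MIR3687-1 at 103, 91.3, 55.1, 71.1 and 153 CPM in the same order. In the batch fit P95H against WT was -0.67 for MIR3648-1 (edgeR adjusted p 4.72e-06) and -0.62 for MIR3687-1 (edgeR adjusted p 9.18e-05). As repeat copies are near-identical, reads cannot be assigned to 1 of them. SREBF1, which encodes a regulator of lipid synthesis genes, stood at 104 and 43.9 CPM in WT, 91.4 and 91.6 CPM in P95H and 182 CPM in the library labelled uninduced. SLC29A2, a nucleoside transporter gene, stood at 31.6, 30.3, 34.7, 38.1 and 67.9 CPM in that order.

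The RNA-seq libraries split by replicate number more than by genotype, with 2867 genes called between the numbers by edgeR. Without mitochondrial genes 2806 were called and at equal depth 2560, so neither abundant mitochondrial transcripts nor depth accounts for the split. Deviations of same-numbered libraries correlated at 0.722 across genes. With 2 libraries per group this restates the split, so it is no separate test of a batch shared by libraries of 1 number. What differed between the batches was not tested, and no biological explanation was tested.

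More HITS-CLIP windows in the authors' deposited table were lower than higher in P95H. Overlapping windows in few genes do not account for the whole of it, since 65.0% of genes with windows in 1 direction were lower, against 77.7% of windows. Windows dominated by 1 library remain open, since the standard errors rule out such a library in 52 of 8100 windows alone, of which 71.2% were lower. Less binding by the mutant or scaling of the libraries could also give the excess. These cannot be told apart, because the authors' deposited table lists 0 windows that missed its threshold.

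Cholesterol synthesis genes were lower in the WT and P95H replicates than in the library labelled uninduced. The batch of the replicate 1 or replicate 2 libraries does not account for the whole of it, since the batch fit called 11 of 16 genes lower in P95H and 12 in WT with that library in the latter, and 9 and 10 with it in the former. For the genes not called with it in the former, such as INSIG1 in P95H, a batch shared with replicate 1 remains open, as does a batch of its own for all. An induction or a label other than stated remains open too, as SRSF2 stood at -0.26 in P95H against that library and did not pass (edgeR p 0.104), with -0.16 and -0.36 without P95H replicate 1 and 2 and -0.19 and -0.34 in the batch fits, the last past the test, and counts cannot tell the construct from the gene. The state of that culture, such as its density or medium, could give the same difference as doxycycline itself, and with 1 library labelled uninduced these cannot be told apart.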
